A study of Mus musculus with 9 samples.

How the data were processed

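RNA from mouse embryonic fibroblasts of 3 genotypes (WT, CK and KO) was measured on 9 Affymetrix arrays, 3 per genotype, after 72 h without serum following culture in 10% serum, per the labels' protocols. Each array measured biotin-labelled cRNA from total RNA. The deposited table holds 34760 probe sets as log2 expression values, made by the authors with RMA and the affy package, per the submitters' processing notes. RMA corrects background, applies quantile normalization between arrays and summarises the probes of a probe set by median polish. The versions, the annotation and any filter were not given in the sources used here. Quantile normalization gives all arrays close to the same distribution, so a change in the total amount of RNA per cell would not be seen. The table has no detection calls, so a low value may be background.

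The deposited values had lost their decimal mark. No cell held a point or comma, and each was a string of 10 to 15 digits. Read with the mark after the 1st digit, strings starting with 1 reached 1.44 at most and all others were 4.28 or more, with no value between. Strings starting with 1 were therefore read as 10 or more, and the others as below 10, which gave log2 values from 4.28 to 14.4. In 2242 pairs of a group and a probe set whose arrays lie on both sides of 10, the median range within the group was 0.263 after this step and 8.92 without it, against 0.133 in all other pairs. The log2 scale itself is taken from RMA in the processing notes.

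Gene names came from the platform annotation supplied with the data. It gives 1 gene symbol for 21640 probe sets, several for 1321 and none for 11799, and only those with 1 symbol were named. Gene identifiers of 21553 of these were found in a RefSeq gene table of assembly GRCm38.p6, which was used only for names, chromosomes and neighbouring genes. These probe sets cover 19937 genes, 954 with more than 1 probe set, for which the probe set with the highest mean was used. Genes with a mean at or above the 40th percentile of genes, a log2 value of 7.24, were tested, which left 11962.

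Values were exactly equal on all 3 arrays of a group for 1.21% of probe sets in WT, 1.47% in CK and 1.31% in KO, among them Cdk6 in WT, where no SD is given. Median polish can give such ties, but their cause was not tested. Without the genes so tied in any group, 11724 genes were left and limma called 5994, 7381 and 7298 of them in KO versus WT, CK versus WT and CK versus KO.

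Groups were compared with limma 3.58.1 in R 4.3.3, with 1 coefficient per genotype over all 9 arrays and empirical Bayes variances (6 residual and 4.1 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were KO versus WT, CK versus WT and CK versus KO, a moderated F-test over the 3 genotypes, and the genes called in the same direction in both mutants. The latter was set beside the overlap of independent lists and beside 100 simulations of unchanged groups against shared WT arrays. Cdkn1b was tested on each probe set with limma and an exact two-sided permutation test.

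Of 1275 entries in 32 gene lists written before the data were examined, 1185 matched a gene. The lists cover the cell cycle, splicing, mitochondria, ribosomes, immediate early genes, matrix and adhesion, cytoskeleton, cholesterol, p53, interferon, cytokines, lysosomes, hypoxia, growth factor signalling, quiescence, Hox genes, genes near Cdkn1b, and markers of other cell types and of sex. The 29 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. Macrophage, neural and sex-linked lists had fewer and are given as values. Named genes were fixed by a rule written before the data were examined. In each comparison it takes Cdkn1b, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members of each list with the smallest p. Symbols that are only clone or model names were not named.

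The fit was tested on simulated data for KO versus WT with 11962 genes, of which 50 were changed at each size. It recovered 24% of genes changed by 0.25 on the log2 scale, 86% of those changed by 0.5 and 100% of those changed by 1 or 2, and called 5 unchanged genes. In the real comparisons a far larger share of genes was called, which loosens the adjusted threshold. The recovered shares therefore do not give the sensitivity of those comparisons. The number of arrays limits the precision, and the median SD within a group was 0.0709 in WT, 0.0849 in CK and 0.0673 in KO. Alternatives were other filters on dim genes, other handling of probe sets, median centring and further quantile normalization, another variance model, fits of 6 arrays, array weights, the replicate number as a block, other thresholds, other list tests, and leaving out each array. A fold threshold of 2 and centring on parts of chromosomes, 3 to each, were chosen after seeing the data. Tables were prepared with Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.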

Results

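Gene expression was measured in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from mouse embryos, of 3 genotypes of Cdkn1b, the gene for the cell cycle inhibitor p27. Wild-type (WT), p27CK (CK) and p27 knockout (KO) cells were each measured on 3 microarrays, 9 in all. The cells had been grown in medium with 10% serum and then kept for 72 h without serum, which makes fibroblasts leave the cell cycle and become quiescent. In published work the name p27CK stands for a p27 protein altered so that it no longer binds cyclins and cyclin-dependent kinases (CDKs); the labels give only the name. The titles call the third genotype KO, while the extraction protocol given for all 9 samples names wild-type or delta51 mice and no other, and does not say which cells delta51 stands for. The comparisons ask how expression in quiescent cells differs from WT in the cells titled KO and in those titled CK, and between these mutants. Median levels of the arrays lay between 7.29 and 7.40 on the log2 scale. Pearson correlations across probe sets were 0.995 to 0.998 between arrays of one genotype and 0.964 to 0.975 between genotypes. The first principal component held 54.7% of the variance and the next 41%, and together they separated the 3 genotypes. The labels do not say whether the 3 arrays of a genotype came from separate cultures or embryos. The p-values below therefore measure only the spread between these arrays, which may be technical, and a genotype cannot be told apart from the cultures that carried it.

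The targeted gene was looked at before any other. Cdkn1b, on chromosome 6, had 2 probe sets with a gene name of their own. The brighter, 10542310, read 11.46 ± 0.04 in WT, 11.10 ± 0.09 in CK and 7.38 ± 0.11 in KO (log2, SD, n = 3). KO arrays were 17-fold below WT (log2 difference -4.09, SE 0.07, limma adjusted p = 2.35e-11), and each KO array lay below every WT and CK array. CK was lower than WT by a smaller amount (log2 difference -0.36, adjusted p = 0.00101) and 13.2-fold above KO. The KO value lies close to 7.24, the 40th percentile of gene means, and is not shown to be above background, so these folds are those of the measured values and not of the RNA. The exact two-sided permutation test of 3 arrays against 3 gave 0.1 for each of these differences, the smallest p it can give. The other probe set, 10542317, was dim in every group, at 7.43 in WT, 7.08 in CK and 7.60 in KO. It did not fall in KO (log2 difference 0.18, adjusted p = 0.0839), and CK read lower than KO on it (log2 difference -0.52). The sources used here do not say which part of the gene the KO allele lacks, whether delta51 names that allele, or which part each probe set covers, so this probe set does not check the deletion.

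**Figure D1:**
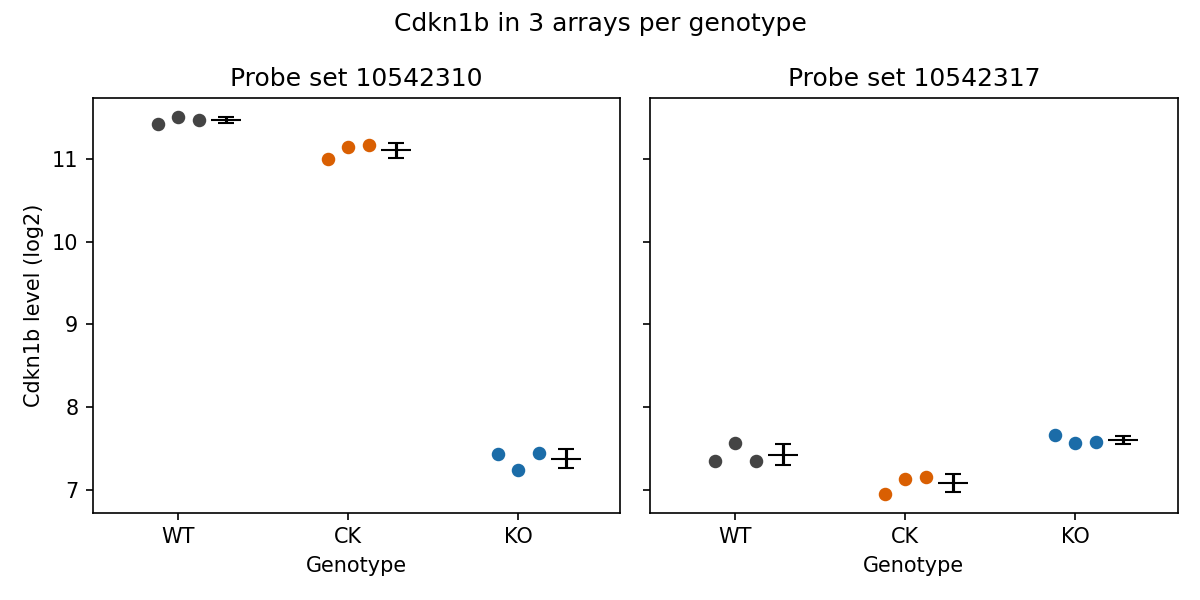
Levels of Cdkn1b (log2, vertical axis) on the arrays of each genotype (horizontal axis) for its 2 probe sets. Points are single arrays and bars show mean ± SD of 3 arrays. On the left, WT and CK arrays read close to 11 and KO arrays close to 7.4, and on the right the 9 arrays read between 6.956 and 7.665.

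In KO cells, several cartilage genes were among those most raised over WT, while a matrix protease, transcription factors and a growth factor were among those most reduced. Gpc3, a cell-surface heparan sulfate proteoglycan, read 12.69 ± 0.03 in KO and 6.62 ± 0.10 in WT (log2, SD, n = 3), a 67-fold difference. Ucma, a secreted cartilage matrix protein, rose by 5.81 (SE 0.15), Cytl1 by 5.79, Dhrs9 by 5.64, and the cartilage matrix protein Matn1 by 5.52 (SE 0.15). Zim1, Palmd, Mab21l2, Sorbs2, the R-spondin receptor Lgr5, Matn3 and the collagen-binding proteoglycan Fmod rose by between 5.52 and 4.41. The deepest fall was that of Mmp3, the matrix protease stromelysin, from 13.13 ± 0.17 in WT to 6.69 ± 1.04 in KO. Egfl6 fell by 6.19 (SE 0.12), the ETS transcription factor Etv1 fell by 5.45, Tenm3 fell by 5.43, the transcription factor Osr2 fell by 5.33 and the glutamate transporter Slc1a3 fell by 5.22. The water channel Aqp1, Inmt, Iqgap2, the retinoic acid binding protein Crabp1, Lhfpl2 and the growth factor Bmp2 fell, with log2 differences between -5.20 and -4.86. In most of these pairs the lower group read near or below 7.24, the 40th percentile of gene means, where background compresses differences, so the folds are those of the measured values.

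Genes of mitosis, the extracellular matrix, cytokines, growth factor signalling and sterol synthesis were lower as groups in KO. Of 64 tested genes of G2/M and mitosis, 32 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.43. Cdc25b, a phosphatase that activates CDKs, fell by 0.78, Pttg1 fell by 0.55, the mitotic kinase Aurkb fell by 0.98 and the kinesin Cenpe fell by 0.79. The list was called lower than other genes (camera adjusted p = 0.00028), but not with an estimated correlation (adjusted p = 0.860). Among 53 genes of DNA replication and G1/S, 17 fell and 6 rose (14 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.274). E2f1 fell by 0.58, Ccne1 fell by 0.74 and Rrm2 fell by 0.86. Of 56 genes of the extracellular matrix and collagens, 36 fell and 7 rose (37 and 8 adjusted over the list alone; camera adjusted p = 2.18e-06, and adjusted p = 0.341 with an estimated correlation). Col18a1 fell by 3.16, the gelatinase Mmp9 fell by 3.37 and Mfap4 fell by 4.56, while Mfap5 rose by 2.44. Of 21 cytokine, chemokine and NF-kB target genes, 17 fell and 2 rose (17 and 3 adjusted over the list alone; camera adjusted p = 2.18e-06, and adjusted p = 0.284 with an estimated correlation). Ptges, a prostaglandin E synthase, fell by 3.23, the monocyte chemoattractant Ccl2 fell by 4.70 and Cxcl16 fell by 2.56. Only 21 of 38 cytokine genes with a probe set passed the filter on dim genes. A high level in 1 group can help a gene pass, so these list values may depend in part on the change itself. Of 43 genes of TGF-beta, BMP and IGF signalling, 26 fell and 5 rose, as they did adjusted over the list alone (camera adjusted p = 0.000125, and adjusted p = 0.314 with an estimated correlation). Igfbp4 fell by 4.55, Inhba fell by 2.67 and Id4 fell by 1.76. Cholesterol biosynthesis genes were lower too, with 15 of 20 reduced and 1 raised (16 and 1 adjusted over the list alone; camera adjusted p = 0.000125, and adjusted p = 0.410 with an estimated correlation). The sterol reductase Tm7sf2 fell by 1.83, Hmgcs1 fell by 0.83 and Cyp51 fell by 0.82.

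Ribosomal, ribosome biogenesis, splicing and cartilage genes were higher as groups in KO. Of 54 cytosolic ribosomal protein genes 44 rose and 0 fell (46 and 0 adjusted over the list alone), with a median of 0.34, and Rps3a1 rose by 1.38 and Rps12 by 0.61 (camera adjusted p = 1.25e-08, and adjusted p = 0.284 with an estimated correlation). Of 57 genes of ribosome biogenesis 42 rose and 0 fell, also adjusted over the list alone, among them Polr1e by 0.78, Utp4 by 0.72 and Nop58 by 0.96 (camera adjusted p = 3.84e-08, and adjusted p = 0.314 with an estimated correlation). Spliceosome genes gave a weaker rise, with 19 of 71 raised and 2 reduced (16 and 1 adjusted over the list alone), led by Sf3a3 at 0.80 and Prpf4 at 0.67 (camera adjusted p = 0.0439, and adjusted p = 0.498 with an estimated correlation). This call was lost without WT replicate 1 (adjusted p = 0.0959), WT replicate 2 (0.0869) or KO replicate 2 (0.0666). Of 11 cartilage and bone markers 9 rose and 1 fell, also adjusted over the list alone, with a median of 2.12 (camera adjusted p = 2.82e-05, and adjusted p = 0.314 with an estimated correlation). Col2a1, the main collagen of cartilage, rose from 9.47 ± 0.04 to 12.67 ± 0.19. A marker that is high in KO alone can pass the filter on dim genes through KO, as Acan did (6.42 in WT, 6.64 in CK and 9.03 in KO). Hapln1, with a difference of -1.55, was not tested. The counts, the median and the camera p of this list therefore depend in part on the change itself.

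Regulators of G1 went both ways in KO. Of 25 G1 cyclins, CDKs and CDK inhibitors, 5 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.572). The G1 kinase Cdk6, which read 10.58 on all 3 WT arrays, fell by 2.58 in KO (SE 0.05), the p27-related inhibitor Cdkn1c fell by 1.41 and the D-type cyclin Ccnd2 fell by 1.01, while Cdkn2a, which encodes the inhibitor p16 and the p53 regulator Arf, rose by 1.12. Of 23 pocket protein, E2F and DREAM genes 6 rose and 6 fell, also adjusted over the list alone, with Hdac1 lower (log2 difference -0.94) and Rbl2 up by 0.50 (camera adjusted p = 0.789). Of 33 immediate early genes 16 rose and 10 fell (18 and 11 adjusted over the list alone), among them Myc, up by 1.24, and Dusp6 at -1.27 (camera adjusted p = 0.572). Of 33 FoxO and quiescence-associated genes 10 rose and 12 fell, also adjusted over the list alone, with Klf15 up by 2.22 and Klf9 at -1.94 (camera adjusted p = 0.649).

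The limma test with Benjamini-Hochberg adjustment called 6129 of 11962 genes between KO and WT, 3184 higher and 2945 lower in KO, which is 51.2% of the genes tested. Of these, 2155 differed at least 1.5-fold, 1049 at least 2-fold (402 higher, 647 lower), 356 at least 4-fold and 50 at least 16-fold. The 3 KO arrays did not overlap the 3 WT arrays for 60.9% of genes, where chance gives 10%. With 3 arrays per genotype the median residual SD was 0.0875, so most calls are differences under 1.5-fold.

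In CK cells, a distal Hox gene, matrix proteins and a protease were among the genes most raised over WT, and a cartilage marker, a transcription factor and several enzymes among those most reduced. Ankrd1, a nuclear ankyrin repeat protein, read 12.16 ± 0.08 in CK and 6.53 ± 0.10 in WT (log2, SD, n = 3). Gpc3 rose by 5.52 (SE 0.07), Cyp4a12b by 5.18, the collagenase Mmp13 by 5.12 (SE 0.35), Hoxd13, a transcription factor of the distal limb, by 4.80, the Wnt modulator Dkk2 by 4.79 and the microfibril protein Mfap5 by 4.61. Egln3, a prolyl hydroxylase of the hypoxia pathway, Lrrc15, the neurturin receptor Gfra2, the matrix protein Dpt and Serpinb9b rose by between 4.50 and 4.21. Cnmd, the cartilage protein chondromodulin, fell from 13.33 ± 0.01 to 7.29 ± 0.17 and the transcription factor Pax9 from 12.66 ± 0.06 to 6.79 ± 0.21. Hpse, which cleaves heparan sulfate, fell by 5.37, Lrrn3 fell by 5.28, Inmt fell by 5.02 and Dio2, which activates thyroid hormone, fell by 4.95. Cd59a, Elovl7, Ramp2, Pcp4, Smpdl3a and Lbp fell, with log2 differences between -4.66 and -4.37. Here too the lower group of most pairs read near or below 7.24, so these are differences of the measured values and not of the RNA.

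Genes of DNA replication were higher as a group in CK than in WT, and those of mitosis less clearly so. Of 53 genes of DNA replication and G1/S 38 rose and 1 fell, also adjusted over the list alone, with a median of 0.45 (camera adjusted p = 3.74e-05, and adjusted p = 0.717 with an estimated correlation). The replicative helicase genes Mcm2 and Mcm7 rose by 0.84 and 1.03 and Dnmt1 by 0.95. Of 64 genes of G2/M and mitosis 24 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 0.0206, and adjusted p = 0.921 with an estimated correlation). H2az1 rose by 1.13, Cks2 by 1.03 and Stmn1 by 1.33, while Cdc25b fell by 1.05. The G2/M call was lost without WT replicate 1 (adjusted p = 0.0762), WT replicate 2 (0.0722), CK replicate 1 (0.0833) or CK replicate 2 (0.0512). Of single genes for inhibitors of the G1 kinases, Cdkn2a rose by 3.17 (SE 0.08) and Cdkn2b by 2.64 (SE 0.07), while Cdkn1b fell by 0.36. In all, 10 of 25 G1 cyclins, CDKs and inhibitors rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.473). Of 23 pocket protein, E2F and DREAM genes 9 rose and 6 fell, also adjusted over the list alone, with E2f3 up by 0.62 and Rbl2 at -0.80 (camera adjusted p = 0.473).

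Ribosome biogenesis, ribosomal, immediate early, hypoxia and Hox genes were also higher as groups in CK, and sterol synthesis genes lower. Of 57 ribosome biogenesis genes 39 rose and 7 fell, also adjusted over the list alone, among them Rrp9 by 1.23, Polr1e by 1.18 and Utp4 by 1.03 (camera adjusted p = 6.04e-05, and adjusted p = 0.694 with an estimated correlation). Of 54 cytosolic ribosomal protein genes 24 rose and 4 fell, also adjusted over the list alone, with Rpsa up by 0.69 and Rplp0 by 0.41 (camera adjusted p = 0.0263, and adjusted p = 0.717 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.0838). Of 33 immediate early genes 20 rose and 6 fell, also adjusted over the list alone, with the stress-induced factor Atf3 up by 2.42 and Ccn2 at -1.59 (camera adjusted p = 0.0111, and adjusted p = 0.586 with an estimated correlation). Of 30 glycolysis and hypoxia genes 19 rose and 2 fell, also adjusted over the list alone, with the glucose transporter Slc2a3 up by 1.84, Pkm up by 1.06 and Aldoc at -3.20 (camera adjusted p = 0.0022, and adjusted p = 0.586 with an estimated correlation). Of 17 tested Hox genes, which encode transcription factors that mark position along the body and limb axes, 11 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0022, and adjusted p = 0.586 with an estimated correlation). Besides Hoxd13, Hoxd10 rose by 3.59, Hoxa9 by 1.98 and Hoxa10 by 1.71. Only 17 of 34 Hox genes with a probe set passed the filter on dim genes. A rise in CK can help a gene pass, so these list values may depend in part on the change itself. Of 20 cholesterol biosynthesis genes 17 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 3.74e-05, and adjusted p = 0.586 with an estimated correlation). Tm7sf2 fell by 3.21, Lss fell by 1.51, Hmgcs1 fell by 1.32 and Insig1 fell by 1.04.

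Matrix and signalling genes went both ways in CK. Of 56 extracellular matrix genes 24 rose and 17 fell, also adjusted over the list alone, with Mmp10 up by 4.17 and Has2 at -2.33 (camera adjusted p = 0.473). Of 43 genes of TGF-beta, BMP and IGF signalling 11 rose and 25 fell (12 and 25 adjusted over the list alone), with Igfbp6 up by 3.19 and Fst at -3.64 (camera adjusted p = 0.0763). Of 21 cytokine genes 8 rose and 11 fell, also adjusted over the list alone, with Ptgs2 up by 1.99 and Cxcl16 at -2.65 (camera adjusted p = 0.898). Of 35 focal adhesion and integrin genes 15 rose and 15 fell (16 and 16 adjusted over the list alone), among them Itga7, up by 2.97, and Itga2 at -2.53 (camera adjusted p = 0.898).

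Between CK and WT limma called 7520 of 11962 genes, 3676 higher and 3844 lower in CK, or 62.9%. Of these, 3025 differed at least 1.5-fold, 1293 at least 2-fold (599 higher, 694 lower) and 343 at least 4-fold. Arrays of the 2 genotypes did not overlap for 67.3% of genes, against 10% by chance.

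Set directly against each other, CK and KO cells had matrix proteases and cartilage genes among the genes that differed most. Mmp3 was higher in CK by 6.26 (SE 0.39), Mmp13 by 5.92, Ankrd1 by 5.32, Cyp4a12b by 5.17, Dkk2 by 4.98 and Cyp2f2 by 4.83, followed by Crabp1, Pgm5, the proteoglycan Vcan, Dpt, Hoxd13 and Renbp, between 4.78 and 4.63. Cnmd was lower in CK (log2 difference -6.55), at 7.29 ± 0.17 against 13.85 ± 0.01 in KO. Cytl1 read 6.99 ± 0.09 in CK and 13.19 ± 0.15 in KO, and Palmd, Matn1, Matn3, Srpx, Sorbs2, Stk32b, Clec11a, Camk4, Cxcl15 and Chodl were lower in CK by log2 differences from -6.02 to -4.17. In many of these pairs the lower group again read near or below 7.24, so the sizes are those of the measured values and not of the RNA.

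Genes of both arms of proliferation were higher in CK than in KO. This held for 40 of 53 genes of DNA replication and G1/S with 0 lower, also adjusted over the list alone, with Cdt1 higher by 1.53, Ccne1 by 1.47 and Pola1 by 1.15 (camera adjusted p = 8.91e-07, and adjusted p = 0.665 with an estimated correlation). It also held for 47 of 64 G2/M genes with 1 lower (51 and 1 adjusted over the list alone), with Stmn1 higher by 2.06 and Cenpe by 1.65 (camera adjusted p = 8.91e-07, and adjusted p = 0.891 with an estimated correlation). Cdk6 was higher in CK by 3.18 (SE 0.05), Cdkn1c by 2.22, Cdkn2a by 2.06 and Cdkn2b by 1.90. Of the 25 G1 cyclins, CDKs and inhibitors 11 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.155). Of 23 pocket protein, E2F and DREAM genes 13 were higher and 3 lower (15 and 3 adjusted over the list alone), and Rbl2, the p130 pocket protein of quiescent cells, read 9.65 ± 0.12 in CK and 10.95 ± 0.05 in KO (camera adjusted p = 0.101).

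Of 56 extracellular matrix genes 41 were higher in CK than in KO and 9 lower (42 and 9 adjusted over the list alone), with Mmp10 higher by 4.42 and Fbln2 by 3.41 (camera adjusted p = 8.91e-07, and adjusted p = 0.463 with an estimated correlation). Of 21 cytokine genes 15 were higher and 4 lower, also adjusted over the list alone, with Ccl2 higher by 4.36, Ccl7 by 4.14 and Ptgs2 by 3.15 (camera adjusted p = 0.000954, and adjusted p = 0.463 with an estimated correlation). Of 30 glycolysis and hypoxia genes 18 were higher and 2 lower, also adjusted over the list alone, with Egln3 higher by 3.31 and Slc2a3 by 2.80 (camera adjusted p = 0.000368, and adjusted p = 0.463 with an estimated correlation). Cytosolic ribosomal protein genes were lower in CK, 27 of 54 with 1 higher (27 and 0 adjusted over the list alone; camera adjusted p = 0.00694, and adjusted p = 0.591 with an estimated correlation), and Rps3a1 gave 10.42 ± 0.19 in CK and 12.11 ± 0.06 in KO. Of 11 cartilage and bone markers 9 were lower in CK and 0 higher, also adjusted over the list alone, with a median of -2.48 (camera adjusted p = 5.36e-06, and adjusted p = 0.463 with an estimated correlation). Col2a1 read 9.04 ± 0.03 in CK and 12.67 ± 0.19 in KO. Markers high in KO alone could pass the filter here too, so these list values depend in part on the change itself. The same may hold for the cytokine genes, of which 21 of 38 with a probe set passed the filter. Of 17 Hox genes 10 were higher in CK and 6 lower, also adjusted over the list alone (camera adjusted p = 0.267). Hoxd13 was higher in CK by 4.68 and Hoxd10 by 3.40, while Hoxa3 read 7.33 ± 0.11 in CK and 9.34 ± 0.14 in KO. In KO against WT 6 Hox genes rose and 2 fell, also adjusted over the list alone, with Hoxa2 up by 2.24, and Hoxa3 and Hoxa6 each up by 1.70 (camera adjusted p = 0.0907).

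Between CK and KO limma called 7439 of 11962 genes, 3532 higher and 3907 lower in CK, or 62.2%. Of these, 3078 differed at least 1.5-fold, 1489 at least 2-fold (845 higher, 644 lower) and 452 at least 4-fold. Arrays did not overlap for 67.5% of genes, against 10% by chance.

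**Figure D2:**
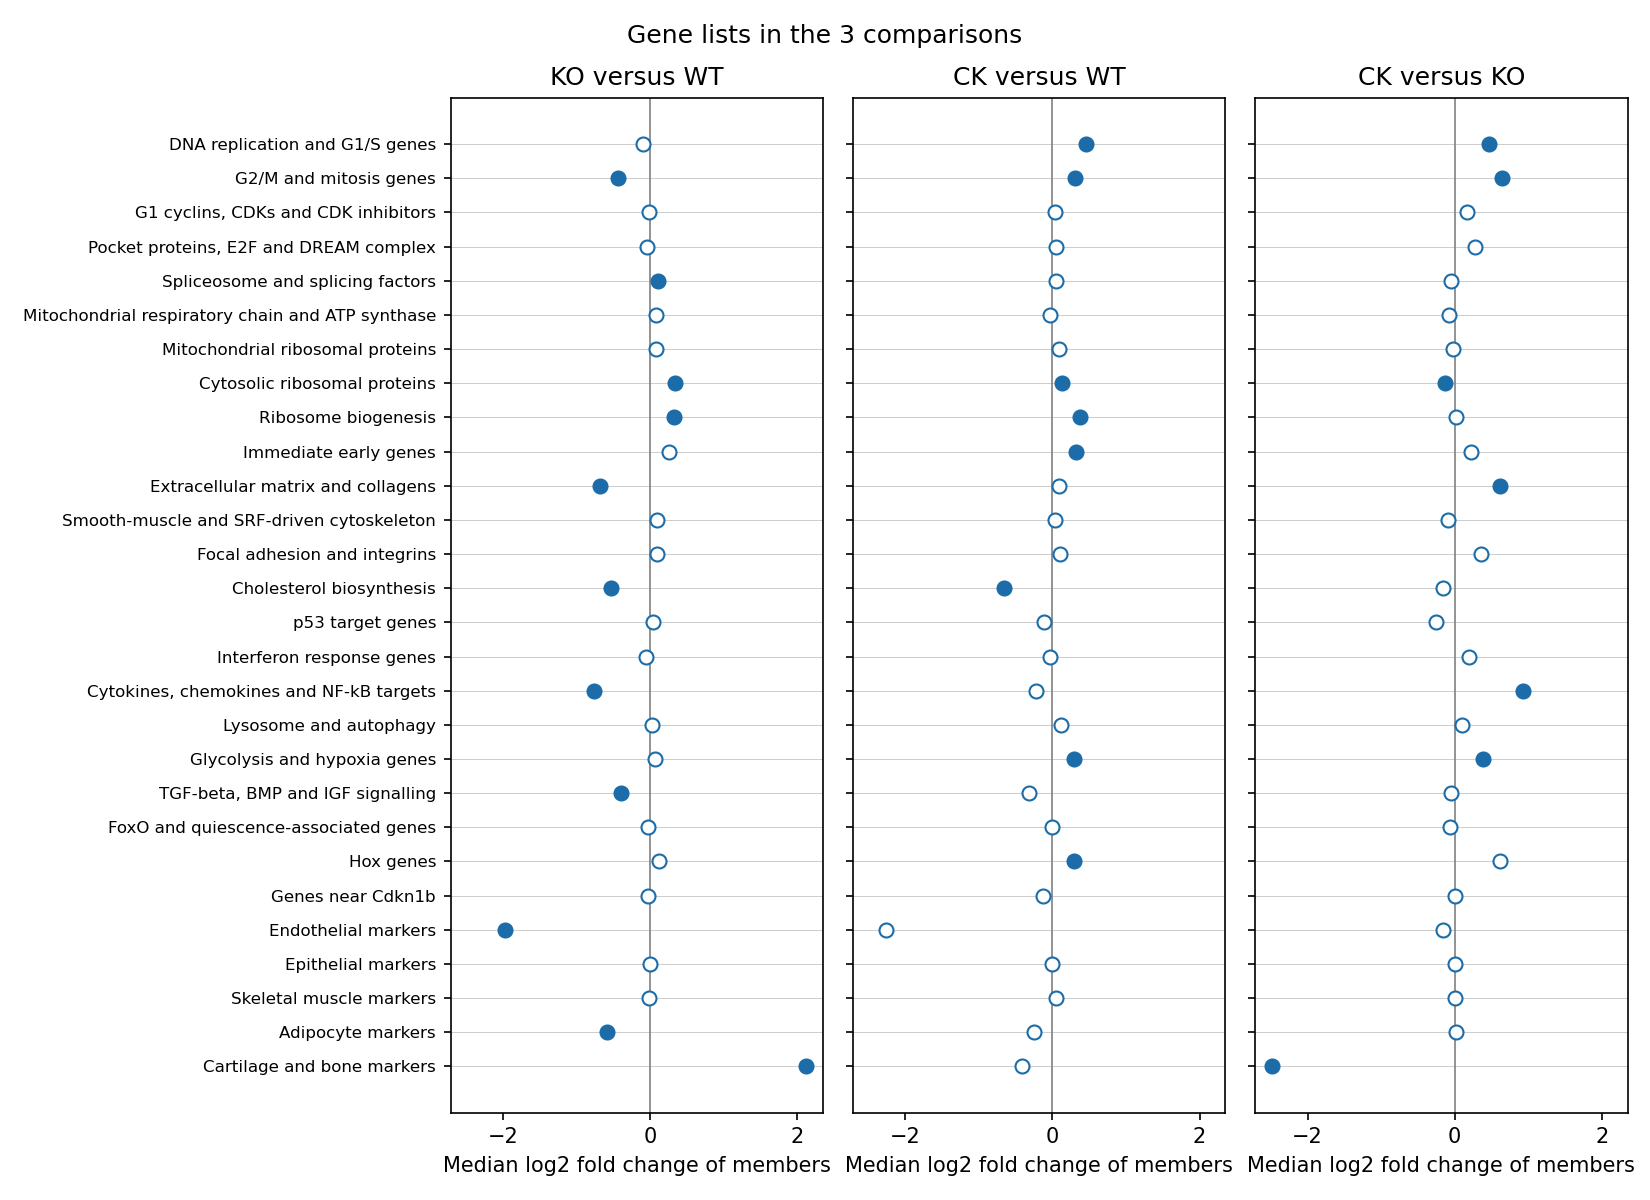
Median log2 fold change (horizontal axis) over the tested members of 28 of the 29 gene lists (vertical axis) in the 3 comparisons. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation of 0.01, and open points are the others. G2/M genes lie at -0.43 for KO versus WT and 0.30 for CK versus WT, and cartilage and bone markers at 2.12 and -0.41.

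Taking the 3 genotypes together, the moderated F-test called 9107 of 11962 genes. Many genes differed from WT in the same direction in both mutants. Among genes changed at least 2-fold in each, 109 were higher in both and 284 lower in both. Gpc3 was higher in KO by 6.07 and in CK by 5.52, Dhrs9 by 5.64 and 3.90, Mab21l2 by 5.42 and 3.41, and Adgrg6, an adhesion receptor, by 4.15 and 3.85. Inmt was lower by log2 differences of -5.19 in KO and -5.02 in CK, Dio2 by -4.66 and -4.95, Pcp4 by -4.48 and -4.57, and Lbp, which binds bacterial lipopolysaccharide, by -4.37 in each. Genes were picked for this comparison after their values were seen, from the 10 in each direction whose smaller change was largest. At any fold, 1575 genes were called higher in both and 1690 lower in both, and 1327 in opposite directions. Independent lists of these sizes would share 978.5 and 946.4 genes in the same direction and 1928.2 in opposite directions. At least 2-fold, independent lists would share 20.1, 37.5 and, in opposite directions, 55.7 genes, where 72 were found. Both comparisons use the same 3 WT arrays, which are too few to split into pairs. The excess over independent lists may therefore come in part or in whole from how those arrays, or the cultures behind them, differ from both mutants. The spread between arrays is argued against as the only source of genes called in both. In 100 simulations of unchanged groups with that spread against shared controls, 0 genes were called in both. These groups held no true differences, so the 0 does not show a common response of the mutants. The fold changes correlated across genes at 0.388, against 0.501 in simulated unchanged groups, and 62.4% had the same sign, against 66.7% simulated. Unchanged groups with shared controls give such values whatever the size of the noise, so they are no benchmark for groups that differ. The correlation and the signs thus do not decide whether the mutants are alike beyond sharing WT arrays. The covariance of the fold changes was 0.206, against 0.0044 simulated, a difference of 0.202, so the spread between arrays gave little of it. Any difference of WT from both mutants raises the covariance, so it does not decide whether the mutants are alike. Genes are not independent replicates.

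**Figure D3:**
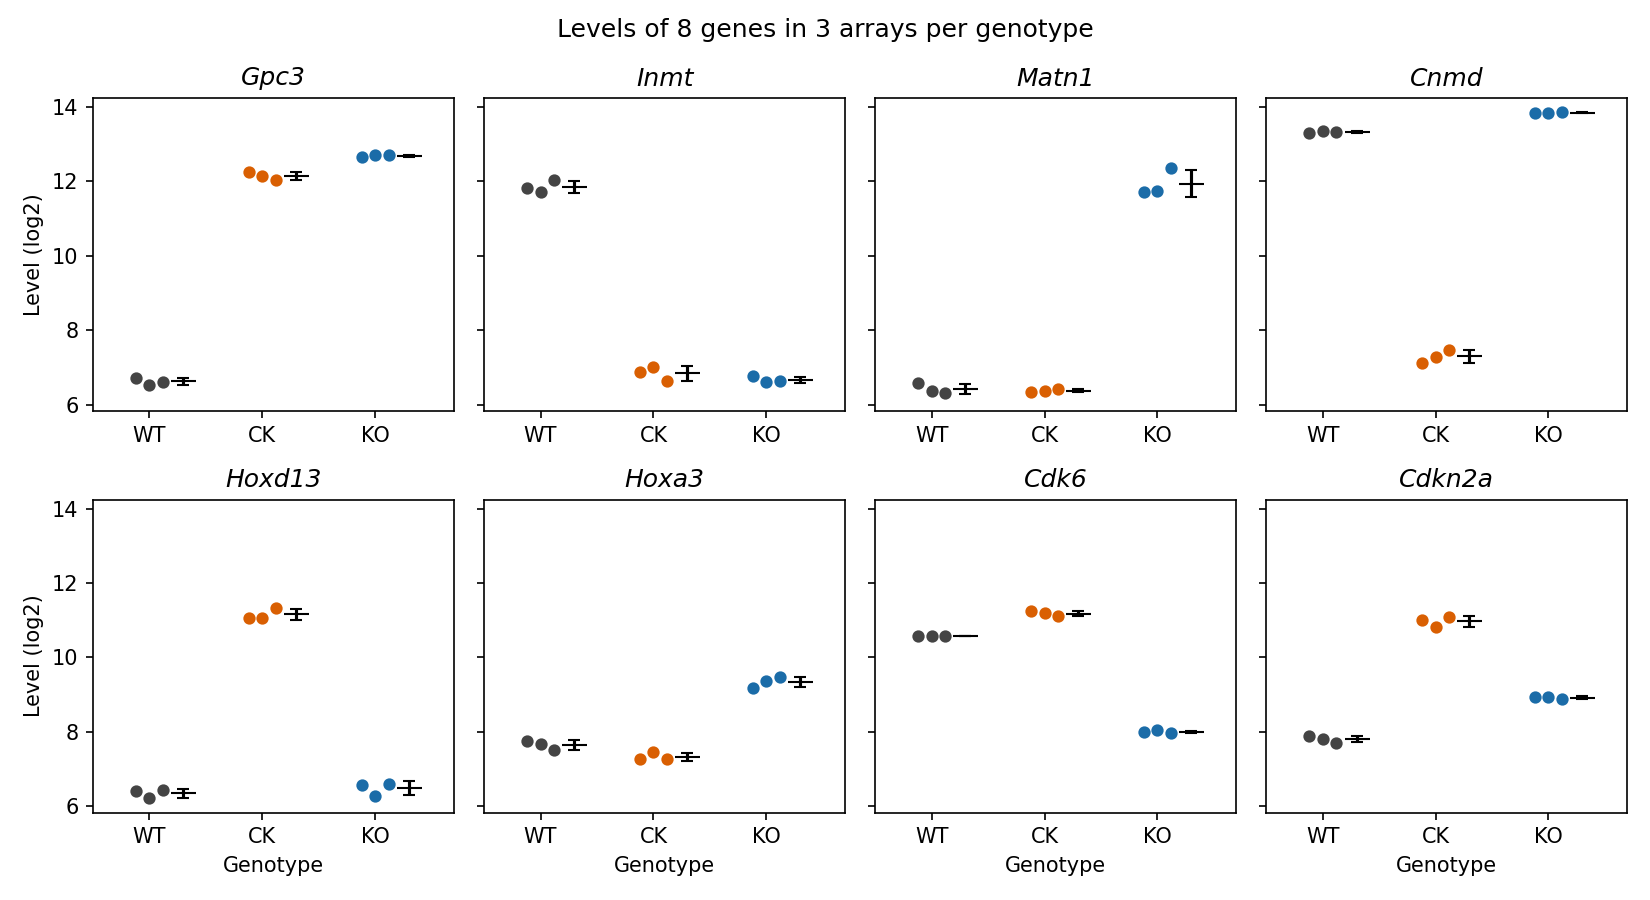
Levels of 8 genes (log2, vertical axes) on the arrays of each genotype (horizontal axes). Points are single arrays and bars show mean ± SD of 3 arrays. Gpc3 and Inmt move together in CK and KO, Matn1 and Hoxa3 are high in KO alone, Hoxd13 is high in CK alone, and Cnmd is low in CK alone at 7.29.

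Markers of macrophages, skeletal muscle and neural cells were dim in all 3 groups. Medians without the filter on dim genes lay between 6.32 and 6.47 for 20 macrophage and leukocyte markers, between 6.77 and 6.81 for 24 skeletal muscle markers, and between 6.43 and 6.61 for 19 neural markers, where the 25th percentile of all genes was 6.34 and the median 8.06. In WT, CK and KO the medians were 7.20, 6.92 and 6.92 for 14 endothelial markers, 6.87, 6.74 and 7.12 for 17 epithelial markers, 7.39, 7.38 and 6.97 for 13 adipocyte markers, and 7.29, 6.99 and 8.39 for 17 cartilage and bone markers. Single members moved with genotype. The lysosomal macrophage marker Cd68 read 10.64 ± 0.09 in WT, 8.59 ± 0.02 in CK and 7.99 ± 0.22 in KO. Lyz2 rose in KO by 1.93, Gap43 in CK by 2.64, and the neuronal protein Map2 fell by 2.94 in KO and fell by 1.22 in CK. Of 5 endothelial markers, 4 fell in KO, also adjusted over the list alone (camera adjusted p = 0.00394, and adjusted p = 0.295 with an estimated correlation), and 3 fell and 1 rose in CK, also adjusted over the list alone (camera adjusted p = 0.176). Ramp2, an adrenomedullin co-receptor, was lower by log2 differences of -4.34 in KO and -4.64 in CK, Eng by -2.69 and -2.85, and Tek by -1.97 and -2.26. Only 5 of 14 endothelial markers passed the filter, and a marker high in WT alone can pass through WT. Tek, for example, read 8.77 in WT and 6.80 in KO, so the counts depend in part on the change itself. Of 8 adipocyte markers 6 fell and 1 rose in KO, also adjusted over the list alone (camera adjusted p = 0.0425, and adjusted p = 0.314 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.117), WT replicate 2 (0.0869) or WT replicate 3 (0.0667). In CK 3 adipocyte markers rose and 4 fell, also adjusted over the list alone, with Lpl up by 2.59 and Pparg at -2.46 (camera adjusted p = 0.835). Of 11 cartilage and bone markers 6 fell and 0 rose in CK, also adjusted over the list alone, with Sox9 lower (log2 difference -0.94) and Alpl at -1.46 (camera adjusted p = 0.0683).

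The remaining lists were not called in any comparison. Of 73 genes of the mitochondrial respiratory chain and ATP synthase 15 rose and 4 fell in KO (10 and 4 adjusted over the list alone), with Uqcrh up by 1.30, and 15 rose and 17 fell in CK (13 and 17 adjusted over the list alone), with Cox5a up by 0.87. Of 75 mitochondrial ribosomal protein genes 18 rose and 6 fell in KO (15 and 5 adjusted over the list alone), with Mrpl50 up by 0.91, and 29 rose and 11 fell in CK (27 and 11 adjusted over the list alone), with Mrps22 up by 0.82. Of 28 smooth-muscle and cytoskeleton genes driven by the factor SRF 9 rose and 8 fell in KO, with Fhl2 up by 1.33, and 13 rose and 11 fell in CK, with Pdlim7 up by 1.13, each also adjusted over the list alone. Of 35 focal adhesion and integrin genes 11 rose and 11 fell in KO (12 and 11 adjusted over the list alone), with Icam1 reduced from 11.77 ± 0.07 to 7.81 ± 0.06. Of 28 p53 target genes 11 rose and 5 fell in KO (12 and 5 adjusted over the list alone), with Btg2 up by 1.62, and 6 rose and 12 fell in CK, also adjusted over the list alone, with Sesn2 up by 1.47. Of 30 interferon response genes 5 rose and 10 fell in KO, also adjusted over the list alone, and 10 rose and 10 fell in CK (11 and 10 adjusted over the list alone), where Cxcl10 rose by 2.88. Of 51 lysosome and autophagy genes 8 rose and 9 fell in KO (5 and 7 adjusted over the list alone), and 19 rose and 9 fell in CK (18 and 9 adjusted over the list alone), with the protease Ctsh up by 1.13 in KO and down from 10.10 to 8.50 in CK. Of 24 genes near Cdkn1b on the chromosome 6 rose and 9 fell in KO and 8 rose and 10 fell in CK, each also adjusted over the list alone, with Mgst1 reduced from 10.85 ± 0.14 to 7.03 ± 0.31 in KO and 8.65 ± 0.03 in CK. Of 6 epithelial markers 0 rose and 1 fell in KO (0 and 0 adjusted over the list alone), and 1 rose and 1 fell in CK, also adjusted over the list alone. Of 8 skeletal muscle markers 1 fell in each mutant, also adjusted over the list alone, and it was Myl4. Xist, the RNA of the inactive X chromosome, read 12.85 in WT, 12.11 in CK and 12.61 in KO, and no transcript of 4 Y-linked genes read over 5.91 on any array.

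Of the 11, 8 and 7 list calls made by camera at the preset correlation in KO versus WT, CK versus WT and CK versus KO, none held with a correlation estimated per list. Camera with the estimated correlation called 0 lists in each comparison, and at an unadjusted p under 0.05 it had 4, 1 and 1. Fry, which asks whether the genes of a list move one way on balance and not whether they differ from other genes, called 18, 20 and 19 of 29 lists. It did not call genes of G2/M and mitosis in KO versus WT (fry adjusted p = 0.108) or in CK versus WT (0.186), but did in CK versus KO (0.0157).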

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

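Of the tests in this part, those on sex, on Hox genes and on gene density outside CK versus WT were chosen after the result was seen, and those on copy number as the only cause and on gene density in CK versus WT after the chromosome shifts were seen but before their own results. Tests of array scaling and of admixed cartilage cells were also run and were dropped after their results were seen, so neither is weighed here. For the first, the median log2 fold changes of all genes were 0.015, -0.011 and -0.019 in KO versus WT, CK versus WT and CK versus KO. For the second, 6 genes of cartilage matrix differed between KO and WT by 3.20 (Col2a1), 2.61 (Acan), 2.12 (Col9a1), 0.63 (Comp), 0.04 (Col9a2) and -1.55 (Hapln1).

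KO and CK differed from WT in opposite directions by at least 2-fold for 72 genes, 30 higher in KO and lower in CK and 42 the reverse. Srpx was higher in KO by 2.17 and reduced in CK (log2 difference -2.89), and Grem1, a BMP antagonist, was higher in CK by 3.34 and reduced in KO (log2 difference -1.20). Genes of G2/M and mitosis had medians of -0.43 in KO versus WT, 0.30 in CK versus WT and 0.65 in CK versus KO, with adjusted p of 0.860, 0.921 and 0.891 with an estimated correlation. Of these 64 genes 7 were called lower in KO and higher in CK, 1 lower in both (Cdc25b) and 1 higher in both, and the others were called in 1 mutant or none. Among probe sets with no or several gene symbols, which no comparison used, 4982 were as bright as the tested genes, and limma called 985 of them in KO versus WT, 1178 in CK versus WT and 1262 in CK versus KO.

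In each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split gave 6129, 7520 and 7439 genes in KO versus WT, CK versus WT and CK versus KO, and the highest other split gave 0 in each, so that 1 of 10 splits gave as many. For gene lists the real values were 11, 8 and 7 and the highest others 13, 11 and 8, and 4, 5 and 4 of 10 splits gave as many. Every other split mixes arrays of both genotypes unequally, so part of the real difference stays in it. The list counts therefore do not decide whether the list calls exceed chance. Over all 9 arrays 1 of 100 splits gave as many genes in the F-test as the real 9107 (highest other 3812), and 2 of 100 gave as many genes changed the same way in both mutants as the real 3265 (highest other 3630). For the F-test a random grouping of single arrays can be excluded at a share of 0.05. At 2 of 100, the count in both mutants was also under that share. It allows no such conclusion, since it depends on which group is the control and the real groups with swapped labels were not drawn. Shuffling single arrays cannot exclude chance differences between cultures. The split with 3630 kept the 3 CK arrays together as controls and mixed WT and KO arrays in the other groups. The number of genes changed the same way can thus be as large where 1 genotype is set against mixtures of the others, and does not by itself show that the mutants are alike.

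Many genes differed between genotypes, with 51.2% to 62.9% of tested genes called, and a difference in embryo sex is argued against, since Xist and Y-linked transcripts differed between groups by at most 0.74 on the log2 scale. Copy number of whole chromosomes, acting on their own genes, is argued against too as the only cause. Of the genes called in CK versus WT 86.1% stayed called with the same sign after the median of each of 3 parts of every chromosome was taken off each array. That step does not remove copy number changes of shorter stretches or their effects on genes elsewhere, so these stay open. Cultures of different position in the body or clonal origin remain a candidate explanation, since 58.8% of tested Hox genes differed at least 2-fold between CK and KO, against 12.4% of all genes (Fisher's exact p = 7.36e-06), with 29.4% against 8.8% in KO versus WT (p = 0.013) and 35.3% against 10.8% in CK versus WT (p = 0.00682). A change in 1 group can help a dim gene pass the filter, and without the filter the shares of 34 Hox genes were 52.9%, 14.7% and 41.2% against 8.2%, 5.8% and 7.3% of all genes in the same order (Fisher's exact p = 1.67e-11, 0.0448 and 3.86e-08), so the evidence was weakest for KO versus WT. Fisher's test takes the Hox genes as independent, which was not tested, so these p-values may be too small. Camera, which asks for a shift in 1 direction, called the Hox list only in CK versus WT (adjusted p = 0.0022). With an estimated correlation, camera gave adjusted p of 0.665, 0.410 and 0.586 in CK versus KO, KO versus WT and CK versus WT. The genotype itself stays open and is confounded with the cultures.

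The median of whole chromosomes shifted in CK or KO against WT. By camera, 10 of 20 had an adjusted p under 0.05 in CK versus WT, 5 in KO versus WT and 6 in CK versus KO. For chromosomes, an estimated correlation and other splits of the arrays were not tested. Among gene lists, no camera call held with an estimated correlation. Other splits gave as many list calls, but they keep part of the real difference and do not decide on chance. The counts of chromosomes therefore do not show that these shifts exceed chance or correlation between genes. Genes of chromosome 9 lay above all genes by a median of 0.213 in CK versus WT, with 0.189, 0.276 and 0.182 in its 3 parts. Those of chromosome 4 stood at 0.2 (0.257, 0.114 and 0.242 in its parts) and those of chromosome 11 at -0.18 (-0.123, -0.309 and -0.101). Both thus shifted the same way in every part, with chromosome 4 at the limit of 0.2 used below. In KO versus WT chromosome 4 had 0.425, 0.236 and -0.039 in its parts and so did not shift as a whole. A shift of gene-dense against gene-poor chromosomes is argued against, since the Spearman correlation of the shift with genes per Mb was 0.077 in CK versus WT (permutation p = 0.752), and it was -0.111 in KO versus WT (p = 0.639) and 0.071 in CK versus KO (p = 0.769). A copy number change of whole chromosomes in a culture may explain the shift of chromosome 9 in CK versus WT, where 0.213 was over 0.2 and each part over 0.1, limits set before the shifts were seen, but the test measures the shift itself, other causes can give the same values, and DNA was not analysed here. Chromosome 18 met these limits in CK versus KO (-0.243, with -0.292, -0.228 and -0.168 in its parts) but not against WT, at -0.163 in CK (-0.271, -0.209 and -0.053 in its parts) and 0.033 in KO, so changes of parts of chromosomes stay open, and an effect of genotype on these chromosomes was not tested.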

How the results depend on the processing

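A fold threshold of 2 and centring on 3 parts of each chromosome were the settings chosen after seeing the data. With a fold change of at least 1.5, the calls were 2155 in KO versus WT (952 higher, 1203 lower), 3025 in CK versus WT (1455 and 1570), 3078 in CK versus KO (1599 and 1479) and 919 the same way in both mutants. With a fold change of at least 2 they were 1049 (402 and 647), 1293 (599 and 694), 1489 (845 and 644) and 393. These counts are lower by construction. Leaving out each array in turn gave 5297 to 6233, 6939 to 7648 and 6786 to 7530 calls in the 3 comparisons, 8553 to 8964 in the F-test, 2837 to 3207 in both mutants, and 8 to 13, 6 to 10 and 7 to 10 called lists. Without the filter on dim genes 11 lists were called in CK versus KO, and the cause was not tested. Camera with an estimated correlation called 0, 0 and 0 lists, fry 18, 20 and 19 for a direction on balance and 28, 29 and 28 for mixed changes; these tests differ by construction. On the second Cdkn1b probe set the difference was reversed, at 0.18 in KO versus WT and -0.52 in CK versus KO, and with the mean of both probe sets it was -1.96 and 1.60; what part of the gene each covers was not tested. Of 427 pairs of a named gene and a comparison 406 were called, and 398 of these kept the call and the sign under every setting that tested them. The fold thresholds and the looser adjusted p were not applied to these pairs. A gene that a filter dropped under a setting was not counted as lost. Deviations of same-numbered arrays correlated from -0.303 to 0.361, with 2 of 9 over 0.1. Both were in KO versus WT, where replicates 1, 2 and 3 gave 0.05, 0.249 and 0.361, while most pairs with CK arrays were below 0. The numbers thus do not pair the samples of all 3 genotypes, but a batch shared by same-numbered KO and WT arrays stays open. With the replicate number as a block 5979, 7377 and 7291 genes were called, of which 5855, 7261 and 7190 were shared with the unblocked calls, and no list call changed. Array weights ran from 0.473 to 6.01. After that centring 88.8%, 86.1% and 88.5% of the calls were kept, with all 26 list calls. The arrays have no detection calls, so signal over background is not known for genes near the dim end.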

Other observations

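The genes named here were chosen after their values were seen. The Wnt receptors Fzd9, Fzd8 and Fzd5 were higher in KO than in WT by 2.55, 1.97 and 1.78 on the log2 scale and lower in CK (log2 differences -1.48, -1.97 and -1.01), and Rspo3, which strengthens Wnt signals, was higher in KO by 1.95 and lower in CK (log2 difference -1.33). Nkd2, a regulator of Wnt signals, went the other way, at -1.73 in KO and 1.40 in CK, and Wnt signalling as a group was not tested. The growth factor Fgf18 was also higher in KO and lower in CK, at 2.10 in KO and -1.72 in CK. The growth factors Hgf and Pdgfd were lower in KO and higher in CK, at -2.60 and -2.59 in KO and 1.67 and 1.20 in CK.

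The rise of cartilage genes in KO did not cover all of them. Of 6 genes of cartilage matrix, Col2a1 differed between KO and WT by 3.20, Acan by 2.61, Col9a1 by 2.12 and Comp by 0.63, while Col9a2 differed by 0.04 and Hapln1, under the filter on dim genes, by -1.55.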
